A study of Oryza sativa with 85 samples.

How the data were processed

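Total RNA from rice inflorescence meristem was labelled with Cy3 and hybridised to 1-colour Agilent arrays of a custom rice design, per the labels and the file headers. The plants of the lines were grown in a paddy field, per the labels. Groups were taken from the sample labels: 3 arrays of Koshihikari, 3 of Habataki and 79 lines with 1 array each, named by line number.

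The deposited scanner files hold spot intensity values from Agilent Feature Extraction version 9.5.3.1, per the file headers. The processed signal is a linear intensity after background subtraction and spatial and multiplicative detrending by that software, with surrogate values for low signals, per the file headers; it is not normalized between arrays. The mean and background signals are raw intensity values per the file headers. The deposited value table is on a log2 scale and was normalized between arrays by the authors with a method that is not given in the sources used here. Within every array its values had a rank correlation of 1 with the processed signal and a slope of 1.00 on the log2 signal in the upper part of the range. Its column medians ran from 8.37 to 9.37, and its scaling between arrays stays unknown.

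Each array has 45151 spots, of which 1417 control spots were left out. Spots flagged as outliers by the scanner software, 881 over all arrays (0.0237%), were removed and filled with the mean of the other arrays of the group. The remaining 43734 probes have 38007 different sequences, 3588 of them on more than 1 spot, and spots of 1 sequence were averaged on the log2 scale. The median SD between spots of 1 sequence within an array was 0.11. The main setting was log2 of the processed signal minus the 75th percentile of its array. The number of arrays limits the precision, and a probe that is not well above background on all arrays of a parent has only a bound there.

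Probes are named by number, and the files give no gene, description or position for them. The reference used here pairs gene identifiers with symbols and holds no probe names or sequences to match, so that none of the 43734 names matched. The 17 gene lists fixed before the data were examined could not be tested, and neither could tests by distance in Mb, correlations between lists or the mean of several probes per gene. Features are therefore probe sequences in place of genes.

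The parents were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05) on the 6 parent arrays, over sequences well above background on at least 2 of 3 arrays of a parent. The mean of the lines was compared with each parent in 1 fit of all 85 arrays, where a sequence above background on at least 8 lines also entered. The variance among lines was set against the variance within parents, moderated with limma's squeezeVar, by a one-sided F test. A sequence went beyond the parents when at least 4 lines lay more than 1 above the highest or below the lowest parent array, the variance among lines was larger and the parents did not differ.

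Markers were sequences with an adjusted p under 0.05 and a parental difference of at least 2. The index of a line is its difference from the Koshihikari mean over the difference of Habataki from Koshihikari, limited to between -0.5 and 1.5 for scores and correlations. The tests by probe number were chosen after the data had been seen. The local score of a sequence is the mean index of markers within 200 numbers, leaving out 5 on each side, with at least 3 markers, and the threshold on r comes from 100 permutations of the lines. Distant association used scores in bins every 100 numbers with at least 5 markers, more than 2000 numbers away, after the local score had been regressed out, with the largest absolute r over bins set against the same in 100 permutations. These steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

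The rule for named probes, written before the data were examined, took the largest changes in each direction among called sequences without overlap between parents and with the brighter parent above background on 3 arrays, the largest differences of the lines from both parents, the largest variance ratios above background on at least 40 lines, and the most lines beyond the parents. Since no probe has a gene name, only the first 2 per direction, or fewer, are named, with their sequences. An at-least fold sets the bright parent's mean against the mean of the dim parent's arrays, each taken at the higher of its own signal and the lowest signal well above background.

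Arrays were on 23 slides scanned on 3 days. Slide 1, scanned on day 1, held replicates 1 and 2 of both parents, and slide 2, scanned on day 2, held replicate 3 of both. Lines were on 21 other slides, 22 lines scanned on day 2 and 57 on day 3.

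The tests were checked on simulated data with 200 changed sequences. Over 32243 sequences with 3 arrays per parent, 34% of changes of 1 and 83% of changes of 2 were called, and 7.14% of calls were unchanged sequences. For the variance test 46% of those given an extra spread of 1 were called, with 6.12% of calls false, and for the lines against Koshihikari 84% of changes of 1, with 3.45% false. Apart from the set changes, the lines in both of these simulations had the spread of the parents and no slide or scan-day shift. In the data the median SD was 0.55 among lines and 0.21 within parents. The rates for the lines against Koshihikari therefore do not describe the real comparison. For the local association over 34286 sequences 99.0% of local effects of 1 were called and 4.31% of calls had no local effect, and a simulated Habataki share of 25.3% came back as an index of 26.0 in percent.

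Alternatives were quantile normalization, normexp (offset 50) with quantile normalization, the authors' value table, no filter and a filter for signal above background on every array, slide or replicate number as a block, all 85 arrays in the parent fit, an intensity trend with robust prior, a minimum change of 1, each parent array left out, other marker choices, values within slides and Spearman correlation. Added after seeing the data were scan day as a block, scan day 2 alone, windows of 100 and 400 numbers, and all counts without 6 lines of low signal or with over 90% of probes above background.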

Results

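Gene expression was measured in rice inflorescence meristem, tissue of the young panicle from which branches and later flowers form. Panicles were 1 to 1.5 mm long, when secondary branches are being laid down. The study compared Koshihikari, a japonica cultivar, with Habataki, an indica cultivar, and with 79 backcross inbred lines derived from a cross of the 2 cultivars. A backcross inbred line carries segments of 1 parent in the background of the other and is close to homozygous after repeated selfing, so that the expression of a gene across lines can be set against the parental segment each line carries. Each parent was measured on 3 arrays and each line on 1 array, 85 arrays in all. Where the labels do not say that the parent samples came from separate plants, p-values measure only the spread between these samples.

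Each array held 43734 probes of 60 bases, with 38007 different sequences, and each different sequence was treated as 1 feature. The share of probes well above background was 83.3% ± 0.699 (SD, n = 3) in Koshihikari and 77.5% ± 0.762 (SD, n = 3) in Habataki, and ran from 69.1% to 94.3% across the lines with a median of 81.7%. Only 1 spot was saturated over all arrays. Levels below are log2 signals minus the upper quartile of their own array, so that a level of 0 is the upper quartile. Across probes, arrays of 1 parent correlated with r between 0.980 and 0.992, and arrays of different parents with r between 0.858 and 0.868; probes are not independent replicates. The files name probes by number only and do not pair them with genes, so that few probes are named, each with its sequence.

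The first comparison asked which transcripts differ between the parents at this stage. Of 32243 sequences tested, 14156 (43.9%) differed between Habataki and Koshihikari with limma's adjusted p under 0.05, of which 6253 were higher and 7903 lower in Habataki. Large differences were mostly lower in Habataki: 2928 sequences were lower by at least 2 on the log2 scale and 618 were higher by as much, so that 82.6% of the large differences were lower. At a difference of at least 4 the counts were 1301 lower and 171 higher. The parents did not overlap, all 3 arrays of 1 lying above all 3 of the other, for 58.0% of the sequences tested, against 10% by chance. The median SD within a parent was 0.20 and the median SE of a difference 0.16.

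Many of the large differences were between a clear signal and none. Among the sequences lower in Habataki by at least 2, 1466 (50.1%) were not well above background on any Habataki array. Among those higher in Habataki by at least 2, 162 (26.2%) were not well above background on any Koshihikari array. Over the sequences above background on all 6 parent arrays, 1085 were lower and 385 higher by at least 2, so that 73.8% of the large differences were lower.

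The direction of the small differences depended on the scaling of the arrays. Quantile normalization moved the median difference over all tested sequences from 0.02 to 0.16, and normexp with quantile normalization moved it to 0.13. The share of calls higher in Habataki was 44.2% in the main setting, 59.3% with quantile normalization and 59.2% with normexp. It was 51.8% with the main scaling over sequences above background on all 6 parent arrays. The share of large differences that were lower in Habataki stayed between 71.9% and 83.3% over these normalizations and the authors' value table.

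**Figure D1:**
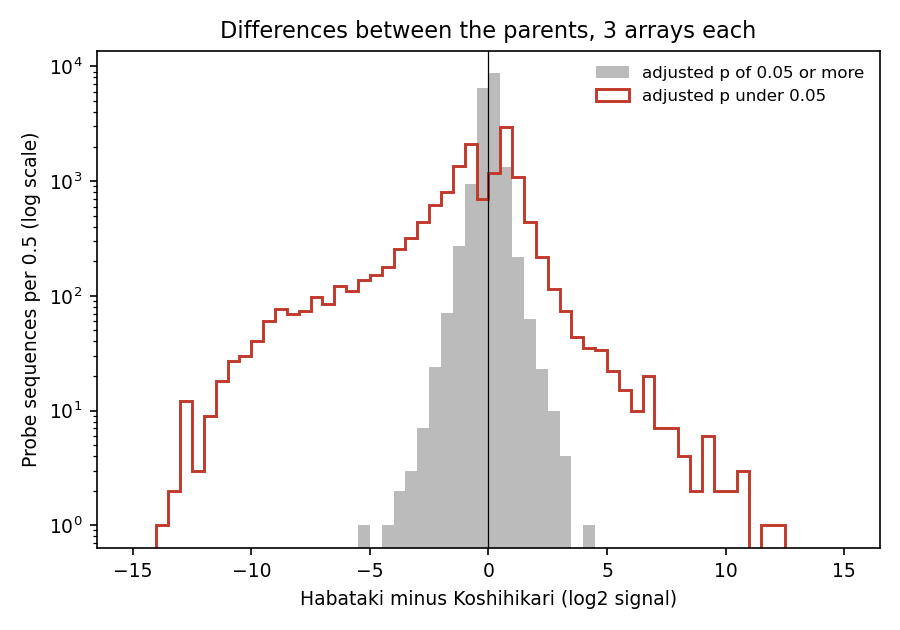
Distribution of the difference between the parents (horizontal axis, Habataki minus Koshihikari, log2 signal) over 32243 probe sequences, with the number of sequences per 0.5 on a logarithmic vertical axis; the red outline holds the 14156 sequences with an adjusted p under 0.05 and the grey bars the others. The left arm, lower in Habataki, is longer and fuller: 2928 called sequences lie at or below -2 and 618 at or above 2.

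The 2 probes named for a fall were near all or none. They have the largest measured log2 differences, but with Habataki not above background their folds are only bounds, and their place in the rank rests on values at background. Probe NIAS06633 (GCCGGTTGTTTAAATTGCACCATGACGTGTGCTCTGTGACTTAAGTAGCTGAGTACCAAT) had a level of 3.71 ± 0.04 (SD, n = 3) in Koshihikari and was not well above background in Habataki, at least 3580-fold lower (limma, adjusted p = 9.49e-08). The fold is a bound taken against the lowest signals well above background on the dim arrays. Probe NIAS30720 (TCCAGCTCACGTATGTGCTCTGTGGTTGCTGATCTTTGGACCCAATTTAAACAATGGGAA) had a level of 3.24 ± 0.19 (SD, n = 3) in Koshihikari and was likewise not well above background in Habataki, at least 2594-fold lower (limma, adjusted p = 9.49e-08). The 2 probes named for a rise ran the other way, with the same limit. Probe NIAS29288 (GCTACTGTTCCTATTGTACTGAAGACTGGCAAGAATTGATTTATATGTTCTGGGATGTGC) had a level of 1.36 ± 0.12 (SD, n = 3) in Habataki and was not well above background in Koshihikari, at least 1003-fold higher in Habataki (limma, adjusted p = 3.3e-07). Probe NIAS16151 (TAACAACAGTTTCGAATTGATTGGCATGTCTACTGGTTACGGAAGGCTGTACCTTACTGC) had a level of 1.23 ± 0.22 (SD, n = 3) in Habataki, at least 918-fold above Koshihikari (limma, adjusted p = 1.2e-07).

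The same 4 probes separated the lines. NIAS06633 was nearer to the Habataki level in 21 lines and nearer to the Koshihikari level in 58, and NIAS30720 in 9 and 70 lines. NIAS06633 was well above background on 70 of the 79 lines and NIAS30720 on 75. Some lines nearer Habataki thus still had a signal that Habataki lacked. NIAS29288 was nearer to Habataki in 24 lines and NIAS16151 in 26. Few lines lay well between the parents: on a scale of 0 for Koshihikari and 1 for Habataki, 1 line lay between 0.25 and 0.75 for NIAS29288, 2 for NIAS30720, 7 for NIAS16151 and 8 for NIAS06633. For all 4 probes 1 end of this scale is a parent not well above background on any array, so that these cuts rest on background values.

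**Figure D2:**
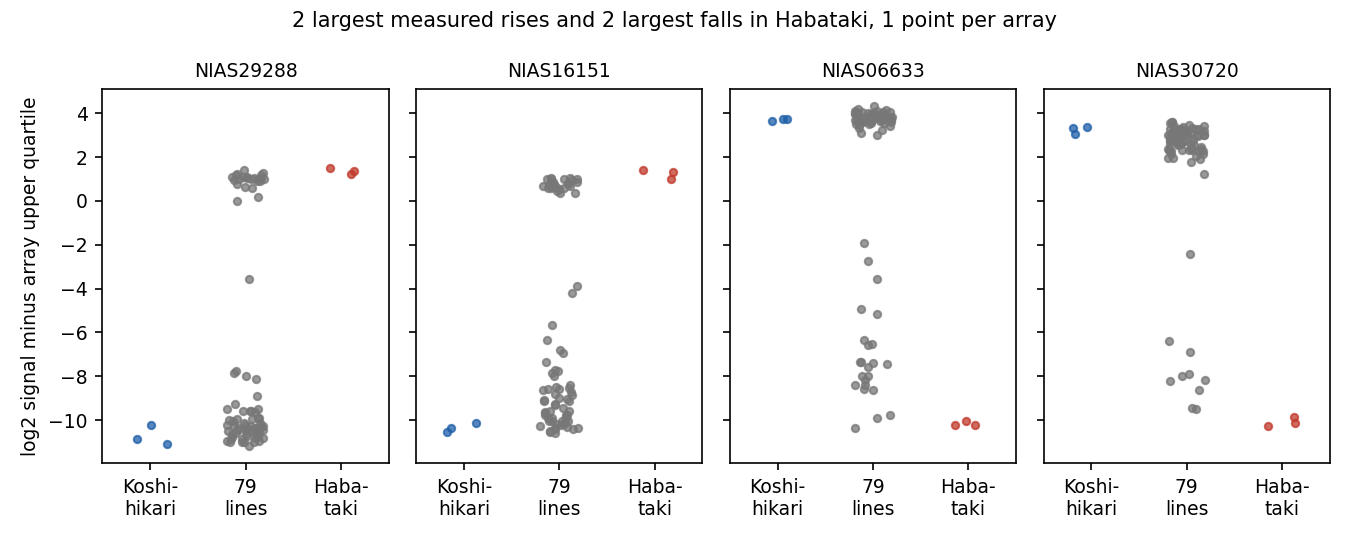
Level of the 2 probes with the largest measured rise and the 2 with the largest measured fall in Habataki (vertical axis, log2 signal minus the array's upper quartile), 1 point per array, for 3 Koshihikari arrays, 79 lines and 3 Habataki arrays. Most lines sit near 1 of the 2 parental levels, with 24, 26, 21 and 9 lines nearer Habataki from left to right.

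Parental differences held on both slides that carried the parents. On slide 1, with 2 arrays of each parent, 11031 sequences were called, and 98.9% of them had the same direction on slide 2, which carried 1 array of each. With slide as a fixed block 16591 were called. The count was 3553 when the lines entered the fit, since the spread among lines then counts as error. Of the 10 ways to split the 6 arrays into 3 and 3, no other split gave a call, but 10 splits are too few for a share under 0.05.

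The next question was where the lines lie between the parents. The 3546 sequences that differed by at least 2 between the parents served as markers, and each line's value was placed on the scale from 0 for Koshihikari to 1 for Habataki. The mean of the lines had a median of 0.258 over markers, with quartiles at 0.159 and 0.366. Single values were mostly near 1 of the parents: 60.7% lay under 0.25, 20.7% over 0.75 and 18.6% between. Markers higher in Habataki gave a median of 0.330 and markers lower in Habataki 0.246. Against the parents and lines of scan day 2 alone the median was 0.256.

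Lines differed widely in the share of markers with a signal nearer Habataki. The share of markers nearer Habataki was 28.5% in the median line, with an SD of 7.86 percentage points over the 79 lines, and ran from 7.05% to 52.4%. It was under 10% in 3 lines and over 40% in 6. On the parent arrays, which were used to choose the markers, the share was at most 0.282% in Koshihikari and at least 99.1% in Habataki.

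**Figure D3:**
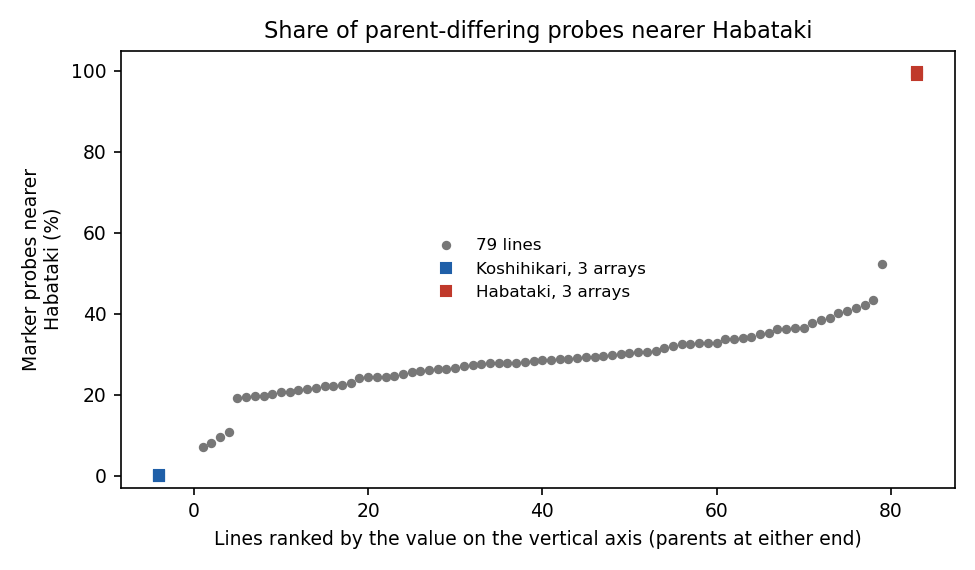
Percent of the 3546 marker probes nearer to Habataki than to Koshihikari (vertical axis) for each of the 79 lines, ranked by that value, with the 3 arrays of each parent at either end. Lines run from 7.05% to 52.4% with a median of 28.5%.

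Markers with close numbers varied together across lines. Pairs of markers 6 to 20 numbers apart had a median r of 0.544 over the 79 lines after each was turned so that Habataki was high. The median was 0.417 at 101 to 200 numbers, 0.131 at 501 to 1000 numbers, 0.040 at 1001 to 2000 numbers and 0.019 at 2001 to 5000 numbers. Over the 31918 pairs 6 to 100 numbers apart it was 0.489, and the highest of 100 random orders of the numbers gave 0.029. Pairs share probes and are not independent. Centring the values within slides gave 0.506, Spearman correlation 0.341, markers above background on every array 0.299 and markers with a parental difference of at least 1 gave 0.240. Probe numbers were therefore used as a coordinate in place of map positions, a choice made after the data had been seen.

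**Figure D4:**
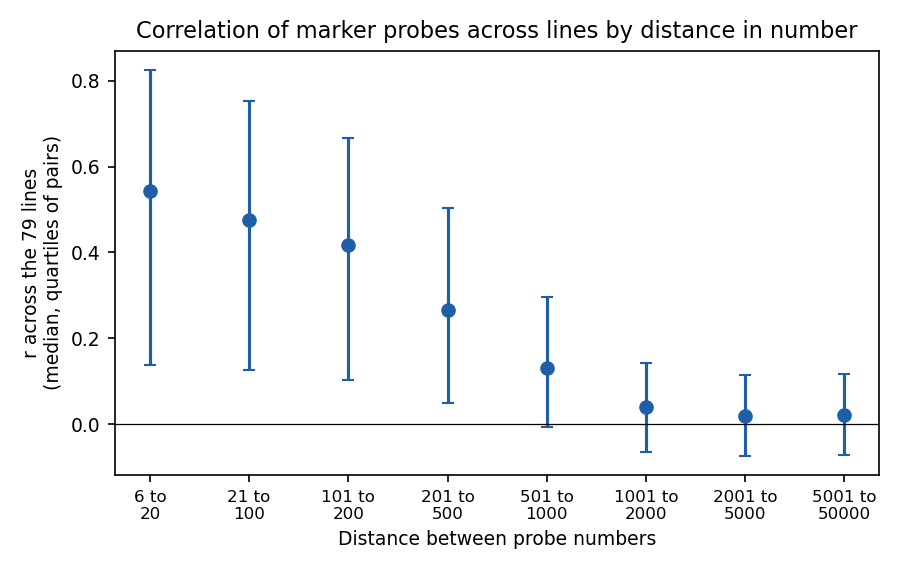
Correlation across the 79 lines between pairs of marker probes (vertical axis, median with quartiles of pairs) against the distance between their probe numbers in 8 classes (horizontal axis). The median falls from 0.544 at 6 to 20 numbers to 0.019 at 2001 to 5000 numbers.

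Signal in the lines was associated with that of markers of nearby number for a large part of the sequences. Each sequence was correlated across the 79 lines with the mean index of the markers within 200 numbers, leaving out those within 5. Of 34022 sequences with at least 3 such markers, 13149 (38.6%) were associated at a false discovery rate under 0.05 over 100 permutations of the lines, at an absolute r of 0.263 or more. Association was found for 2868 of 3558 sequences (80.6%) that differed by at least 2 between the parents, for 47.7% of those with a smaller called difference, and for 26.5% of those without one. Among associated sequences with a parental difference of at least 2, 99.3% went the way of the parents, and the median share of variance explained over all 3558 was 51.5%. Over the 20084 sequences without a called parental difference, 5325 of which were associated, that share was 2.38%. Permuting the lines does not guard against a factor that acts on a whole array, so that a parental type is not shown for these. With the filter that asks for signal above background on all 85 arrays, 8631 sequences were associated.

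The Habataki-like share was uneven along the probe numbers. In 85 windows of 500 numbers the percent of marker values nearer Habataki had a median of 27.5, with quartiles at 24.4 and 32.3 and a lowest value of 16.7. The highest value, 51.2, was in the window of numbers 12500 to 12999, with 29 markers, and the windows on either side had 44.2 and 43.0.

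**Figure D5:**
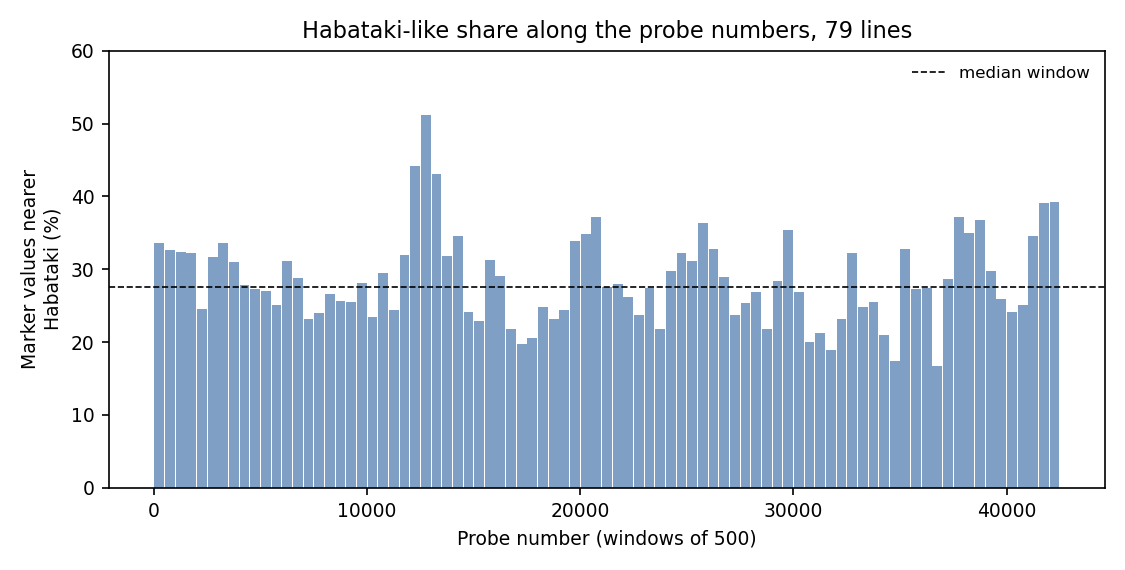
Percent of marker values nearer Habataki over the 79 lines (vertical axis) in the 85 windows of 500 probe numbers with at least 5 markers (horizontal axis); the dashed line is the median window, 27.5%. The highest bar, 51.2%, covers numbers 12500 to 12999.

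Transcripts varied more among lines than among arrays of 1 parent. Of 34286 sequences, 18318 (53.4%) had a larger variance among the 79 lines than within parents by a one-sided F test with limma's moderated variance (adjusted p under 0.05), and the median ratio was 5.40. The median SD was 0.55 among lines and 0.21 within parents. The variance was larger for 92.9% of the sequences that differed by at least 2 between the parents, for 79.1% of all with a called parental difference and for 35.7% of the others. The probe named for its ratio was NIAS13690 (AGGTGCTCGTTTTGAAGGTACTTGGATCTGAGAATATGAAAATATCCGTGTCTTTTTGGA), with a ratio of 1986, which rests partly on background values: it was well above background on 55 of the 79 lines, and normexp gave 636. It had a level of 0.69 ± 0.02 (SD, n = 3) in Koshihikari, was not well above background in Habataki, and reached 4.18 in the highest line. Among the 79 lines 19 exceeded every parent array of NIAS13690 by more than 1. The lines were on other slides than the parents, but arrays of lines on 1 slide shared a consensus correlation of only 0.055, and 17144 sequences were called from the variance within slides. Without replicate 2 of Koshihikari 11620 were called. Array quality also varied more among lines. The percent of probes well above background had an SD of 3.47 over the lines, against 0.699 in Koshihikari and 0.762 in Habataki. Each line had 1 array, so that line, sample and array quality cannot be told apart in the variance among lines.

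Many transcripts that did not differ between the parents went beyond both of them in some lines. Of the 7237 sequences with a larger variance among lines and no called parental difference, 3856 had at least 4 lines more than 1 above the highest or below the lowest parent array. Of these, 2514 had such lines above, 1812 below and 470 both. NIAS13511 (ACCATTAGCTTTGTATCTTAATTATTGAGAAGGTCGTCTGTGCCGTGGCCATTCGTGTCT) lay beyond the parents in most lines, above in 62 and below in 6, with a level of -0.15 ± 0.04 in Koshihikari and 0.06 ± 0.52 in Habataki (SD, n = 3 each) and 1.88 ± 1.78 (SD, n = 79) in the lines. NIAS18902 (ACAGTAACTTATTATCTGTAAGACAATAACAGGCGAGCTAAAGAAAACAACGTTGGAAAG) was below both parents in 69 lines, with 0.86 ± 0.26 in Koshihikari and 0.60 ± 0.13 in Habataki (SD, n = 3 each) and -2.06 ± 1.22 (SD, n = 79) in the lines.

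These transcripts moved partly with the quality of the arrays. The first axis of the 3856 sequences held 26.1% of their variance over lines. Across the 79 lines its absolute Pearson r with the percent of probes well above background was 0.547 (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 3e-05 over 3 measures), with a Spearman rho of 0.312 (permutation p = 0.0053). The r was 0.475 without the 2 lines farthest from the median and 0.551 within slides. With the log2 upper quartile signal r was 0.431 (permutation p = 0.00028, adjusted p = 0.00042), rho was 0.303 (permutation p = 0.0068), and r was 0.373 without the 2 farthest lines and 0.480 within slides. With the share of markers nearer Habataki r was 0.210 (permutation p = 0.063, adjusted p = 0.063), rho was 0.163 (permutation p = 0.15), and r was 0.174 without the 2 farthest lines and 0.086 within slides. With normexp background correction 1983 sequences went beyond the parents, and with signal above background on every array 1862.

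The mean of the lines was closer to Koshihikari than to Habataki. By limma 591 of 34286 sequences (1.72%) differed between the lines and Koshihikari, 550 higher and 41 lower in the lines, and 6993 (20.4%) differed between the lines and Habataki, 3862 higher and 3131 lower. The balance of directions depended on the scaling of the arrays. The share of calls higher in the lines than in Habataki was 55.2% in the main setting, 31.4% with quantile normalization and 28.4% with normexp; against Koshihikari it was 93.1%, 90.1% and 82.7%. With signal above background on every array the share higher than in Habataki was 43.3%. The median absolute difference was 0.29 from Koshihikari and 0.41 from Habataki. Whether these 2 counts differ beyond chance was not tested. Lines and parents shared no slide, and only scan day 2 held both. With scan day as a block limma called 0 sequences against Koshihikari, with 747 at an unadjusted p under 0.05, and 334 against Habataki, with 5322 at an unadjusted p under 0.05. The sequences called against Koshihikari, each turned so that its difference is positive, differed by a median of 1.63 from the slide 1 arrays of Koshihikari and 0.32 from its slide 2 array, with the same direction for 85.8%. Those called against Habataki differed by 1.28 from its slide 1 arrays and 1.01 from its slide 2 array, with the same direction for 97.5%; all parent arrays had been used to call them. Without 1 of the 2 slide 1 arrays of Koshihikari 73 or 121 sequences were called, and without its slide 2 array 864. Against Habataki 2835, 1730 and 4055 were called without its replicate 1, 2 or 3.

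A set of 224 sequences differed from both parents in the same direction, 211 higher and 13 lower in the lines. Both comparisons share the same lines. Independent lists of these sizes would share 62.0 higher and 3.74 lower sequences, and 20 draws of 6 lines set as 2 unchanged parents gave 0. Neither value allows for the layout of the parents, in which 4 of the 6 arrays share slide 1 and its scan day, so that neither is the count to expect without a change. The median difference of the 211 higher sequences from the slide 2 parents was 10.8% of that from the slide 1 parents. Sequences were ranked by the smaller of the 2 differences. The first among the higher was NIAS13395 (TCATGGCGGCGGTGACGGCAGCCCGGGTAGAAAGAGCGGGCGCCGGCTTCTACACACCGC), at 3.68 ± 0.66 (SE) from Koshihikari (limma, adjusted p = 0.00014) and 3.73 ± 0.66 (SE) from Habataki (limma, adjusted p = 2.5e-05). With scan day as a block these differences were -0.11 (adjusted p = 1.00) and -0.057 (adjusted p = 0.98). Its mean was -6.23 over the 4 parent arrays of slide 1, -1.16 over the 2 parent arrays of slide 2 and -0.83 over the lines. Without Koshihikari replicate 1 or 2 its difference from Koshihikari was 2.78 and 2.88 (limma, adjusted p = 0.19 and 0.088). Without replicate 3 it was 5.38 (limma, adjusted p = 9.3e-08). The probe was well above background on only 2 Habataki arrays, so that its difference from Habataki is a bound. By the same rank NIAS18902, described above, came first among the lower: lines minus Koshihikari was -2.92 ± 0.69 (SE; limma, adjusted p = 0.0081) and lines minus Habataki -2.66 ± 0.69 (SE; limma, adjusted p = 0.0040). With scan day as a block they were -3.46 (adjusted p = 1.00) and -3.21 (adjusted p = 0.085), and without Koshihikari replicate 1, 2 or 3 the adjusted p against Koshihikari was 0.17, 0.13 and 0.056. The differences from Koshihikari in those 3 fits were -3.04, -2.94 and -2.78, so that the call was lost but not the difference. Its parents were at 0.66 on slide 1 and 0.87 on slide 2.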

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

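Of 367 alternative values 338 stayed within the limits set for them, which for a count say nothing of its directions. All 124 for the 8 probes named between the parents kept their direction and side of the threshold. Of 117 for the 5 probes named for the lines, 104 did, 9 lost the call and 4 reversed. With scan day as a block NIAS13395 moved to -0.11 from Koshihikari and -0.057 from Habataki, and NIAS36949 to 0.87 and 0.13. NIAS18902 lost its call against both parents there, with differences of -3.46 from Koshihikari and -3.21 from Habataki. In the main setting they were -2.92 and -2.66. With quantile normalization, normexp and signal above background on every array the majority of calls turned between the parents, to 59.3%, 59.2% and 51.8% higher in Habataki, and for the lines against Habataki, to 31.4%, 28.4% and 43.3% higher in the lines. Scan day as a block, scan day 2 alone, the share of large differences lower in Habataki, the tests by probe number and the values without the 6 doubted lines were chosen after the data had been seen. The parental count was 3553 with all 85 arrays in the fit, where the lines' spread counts as error, and 7227 with a minimum change of 1, which leaves fewer sequences by construction. It was 15330 with the replicate block and 9937 to 15007 with 1 parent array left out. Same-numbered parent arrays deviated together with correlations of 0.089, 0.177 and 0.493, but not every array correlated best with its own number. The numbers were therefore not taken to pair the samples. The correlations followed the slide, with its scan day. Pairs of arrays on the same slide ran from 0.083 to 0.493, and pairs across slides from -0.336 to -0.149.

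The counts of the lines against the parents were the least stable. Against Koshihikari, 591 sequences in the main setting became 382 with a minimum change of 1, 945 without the 6 doubted lines, 0 with scan day as a block and 73 to 864 with 1 parent array left out. Against Habataki, 6993 became 4011 with a minimum change of 1, 334 with scan day as a block and 1730 to 6896 with 1 parent array left out. For the single arrays and the block the cause of the lower counts was not tested. The 18318 sequences with larger variance became 15485 without the 6 doubted lines and 11620 to 20590 with 1 parent array left out, the lowest without Koshihikari replicate 2. The 3856 sequences beyond the parents became 1983 with normexp and 1862 with signal above background on every array, 2683 without the 6 doubted lines, and 3567 to 4473 with 1 parent array left out; for normexp the cause was not tested, while the strict filter leaves fewer sequences by construction. The median index stayed between 0.246 and 0.330 over all its alternatives and between 0.252 and 0.263 with 1 parent array left out. The co-segregation of markers 6 to 100 numbers apart stayed between 0.240, with markers of at least 1, and 0.680, with normexp. Local association gave 8631 with signal above background on every array, which leaves fewer markers and sequences, and 11805 to 14048 in its other alternatives.

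Not run for want of gene names or positions were the gene lists and their correlations with all alternatives, the mean of probes per gene, and windows in Mb. Slide as a fixed block could not be fitted for lines against parents, which share no slide. For the probes outside the 77.5% and 83.3% above background in the parents the signal was not well above background, and a difference there is only a bound.

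In 100 splits each, only the real one reached the 6993 calls against Habataki or the 18318 with larger variance. The highest other counts were 4202 and 658. Other splits set mostly different lines in place of 3 arrays of 1 cultivar, so that chance is not tested. Lines and parents share no slide. The 591 calls against Koshihikari were reached by 3 of 100, the highest other 1179 from 3 lines, 1 of them doubted. Trios of lines alone can thus give as many, up to 2523 on 2 slides. For the 14156 parental calls 1 of 10 splits, the real one, gave as many, the highest other count was 0, and 10 splits are too few for a share under 0.05.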

Other observations

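Every test of an explanation in this part was chosen after the results it bears on had been seen. Signal in the lines was also associated with markers far from the probe's own number. After the local score had been regressed out, 11101 of 34286 sequences had an association more than 2000 numbers away at a false discovery rate under 0.05, with an absolute r of 0.428 or more. As for the local association, permuting the lines does not guard against a factor that acts on a whole array. An effect of the distant region is therefore not shown for these sequences. The positions of the strongest association were uneven: 7 windows of 500 numbers held 7494 of these associations, led by 1849 in the window that starts at 32000 and 1366 in the one at 33500. Permuting the lines jointly, which keeps the correlation between transcripts, gave a largest window of up to 482 in 95% of 100 permutations but of 2064 in the most extreme one, so that a single large window alone does not exclude chance.

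A small group of 97 sequences had a distant absolute r of at least 0.8. Of these, 78 differed by at least 2 between the parents, and 7 also followed the markers beside their own number. NIAS23336 (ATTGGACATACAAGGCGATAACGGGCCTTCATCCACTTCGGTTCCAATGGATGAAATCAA), 9.29 higher in Habataki on the log2 scale and above background on all 6 parent arrays (limma, adjusted p = 9.6e-08), was nearer Habataki in 16 lines, had a distant association and did not follow the markers beside its number. NIAS15497 (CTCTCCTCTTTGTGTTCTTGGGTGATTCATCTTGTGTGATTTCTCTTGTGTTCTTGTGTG), with the largest fall among probes above background on all 6 arrays, -11.62 (limma, adjusted p = 1.4e-07), was nearer Habataki in only 4 lines. Unlike NIAS23336, it followed the markers beside its number, and it had a distant association as well. Neighbouring bins 400 numbers apart had a median r of 0.659 over the lines, and r fell under 0.3 in 14 separate stretches of numbers. The most alike pair of lines had r = 0.740 across markers, which are not independent, against a median of 0.140 over 3081 pairs of lines.

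Large parental differences were mostly lower in Habataki. Scaling of the arrays is argued against as the whole account, since the lowest share under another normalization was 71.9%. A mismatch or loss of the probe target in the indica parent would act at the probe's own locus, and 83.3% of the sequences lower in Habataki by at least 2 followed the markers beside them, as this needs. A difference in expression set at the locus predicts the same, and 68.2% of the sequences higher in Habataki, which a mismatch to Habataki cannot give, followed the markers beside them as well. A mismatch or loss of the target in Koshihikari could give these, so that they do not show a difference in expression. Of them 162 (26.2%) were not well above background on any Koshihikari array. Loss of the target and expression may both contribute, and without the 2 genome sequences at the probe sites their parts stay open.

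The window of probe numbers 12500 to 12999 was nearer Habataki in more lines than any other of the 85 windows, with 46 of 79 lines scoring over 0.5 where 18.2 would be at their own overall shares. A shift of the line arrays against the parents would move markers higher and lower in Habataki apart. Both lay above their overall percent, by 35.1 and 18.1 percentage points. The window was chosen as the highest by these same values, which raises both, so that this is only weak evidence against a shift. Within scan day 2 the window was still 18.9 percentage points over the median window, which differences between scan days alone would not leave. That day holds 22 of the same 79 lines, so that this is no separate evidence for the window. A candidate explanation is that the lines carry more Habataki segments in this region than elsewhere (adjusted p = 2.7e-10 over 85 windows, taking lines as independent), by chance in the early generations or by selection; these were not told apart, and 8 windows in all passed 0.05.

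The 211 sequences higher in the lines than in both parents may reflect the slide and scan day of replicates 1 and 2 of the parents. The median difference of the lines was 1.76 from the 4 parent arrays of slide 1 and 0.19 from the 2 parent arrays of slide 2, which is 10.8% of the former, and all 211 were nearer to the slide 2 parents. Within scan day 2, 10 of the 211 (4.74%) kept at least 50% of both differences, but that day holds 1 array of each parent, the same as on slide 2, so that this is no separate evidence and a higher level in the lines stays open. Slide, scan day and the parent samples put on slide 1 cannot be separated here. Of the 13 sequences lower than both parents, 10 were nearer to the slide 2 parents as well, with a median difference of -0.96 from slide 1 and -0.36 from slide 2. NIAS36949 (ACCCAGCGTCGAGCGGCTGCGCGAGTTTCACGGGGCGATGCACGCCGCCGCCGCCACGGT) had parents at -1.91 on slide 1 and -6.08 on slide 2 and lines at -5.61, whereas NIAS18902 had parents above the lines on both slides.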
